A study of Saccharomyces cerevisiae with 48 samples.

How the data were processed

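The series holds 48 libraries from budding yeast: 24 immunoprecipitates (IP) with a peak list each and 24 inputs, which were not analysed here. Of the peak lists, 4 come from chromatin immunoprecipitation of Rpb1, the largest subunit of RNA polymerase II, and 20 from pull-down of DNA carrying biotinylated trimethylpsoralen (bTMP), a compound that intercalates preferentially into under-wound DNA. Groups were taken from the labels: strain (wild type, sen1, rrm3, sen1rrm3, alone or with top1 or top2-1) and growth condition. S-phase cultures were collected 45 to 50 min after release from alpha-factor at 23 °C. Log cultures grew 2.5 h in YPD. The 32 °C cultures grew 1.5 h at 25 °C and then 1 h at 32 °C. top2-1 is a temperature-sensitive allele. Each group has 1 library, so there are no replicates, and the paired tests below treat different strain backgrounds as the repeats of a contrast.

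Per the submitters' processing notes, Bowtie2, Picard, SAMtools and deepTools were used, without versions. The peak caller, its settings and the genome build are not given in the sources used here. The deposited files are peak lists called per library, with chromosome, start, end, a peak name and a score. The deposited score of each peak is the authors' own value, its meaning is not stated, and it was used here only to rank peaks within a list. Read depth is unknown, so a list's length and covered share can reflect sequencing depth and caller settings as well as the cells. Confidence intervals given for shares of peaks or genes are exact 95% binomial intervals and cover counting error only.

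Peak positions were assigned to the genes of the RefSeq table of assembly R64, used for gene names, neighbours and class membership, with strand read from the systematic names. Because no source names the build, the assignment was checked on the files. Ribosomal protein genes were moved along the chromosomes in steps of 10 bp up to 1000 bp each way. Their cover by wild-type Rpb1 peaks was highest at shifts from -10 to 50 bp, at 99.4% of their base pairs, and on 15 of the 15 chromosomes with covered genes of this kind the unshifted position was among the best. At a shift of 400 bp, cover dropped to 86.0% of the best value in one direction and 80.2% in the other. Differences between builds smaller than this plateau, or away from these genes, would go unseen. Coordinates printed are those of the deposited peaks, counted from 1. The nuclear genome was taken as the 16 chromosomes up to the last annotated gene or peak, 12.1 Mb in all. Mitochondrial peaks were left out.

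Feature classes and 15 gene lists were fixed before the data were examined, together with the tests, the rule for named genes and most alternatives. Of the 16 classes planned, replication origins, the middle of inter-origin stretches and Ty or LTR elements were not analysed here because the annotation used does not mark them. The rDNA repeat was left out of the sen1 and rrm3 tests because 1 list has no peak over it, which leaves 12 classes. Centromeres were replaced by the interval between the innermost genes of the left and right arms. All 643 list members were found in the gene table. The lists were histone, G1/S, G2/M, M/G1, pheromone-response, ribosomal protein, glycolysis, galactose, ribosome biogenesis, Nrd1-Nab3-Sen1 attenuated, heat-shock and DNA-damage-response genes, the strain loci, snoRNA genes and tRNA genes.

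Relative coverage is the share of a class's base pairs under peaks divided by the share of the nuclear genome under peaks. tRNA genes were widened by 100 bp on each side, promoters were the 300 bp upstream of protein-coding genes and gene 3' ends the 300 bp downstream. bTMP contrasts were tested on log2 covered share and log2 relative coverage with a two-sided exact sign-flip permutation test over pairs of libraries differing in 1 mutation or condition. The 10 sen1 pairs and the 10 rrm3 pairs allow a smallest p of 0.00195. The 4 pairs of each other contrast allow 0.125 and the 5 squares of the interaction 0.0625, so those cannot reach 0.05. Classes were adjusted together by Benjamini-Hochberg. Rpb1 classes were set against 1000 circular shifts of each list within chromosomes, as a description of that list. A gene was gained when at least 50% of its body lay under mutant peaks and 0% under wild-type peaks, and lost in the reverse case. List means were set against 10000 random lists matched on wild-type cover. A bTMP gene (body plus 300 bp upstream) was consistently changed when its cover differed by at least 10 percentage points the same way in at least 7 of 10 pairs and the other way in at most 1. These counts were compared with 100 sign patterns of the pairs, the real one included. For Rpb1, the text names the 8 gained and 8 lost genes with the most base pairs under peaks per mutant, plus list members gained or lost, up to 6 per list, and the strain loci. Not all genes that the rule takes are printed. For bTMP it draws on the 8 higher and 8 lower genes with the most concordant pairs per mutation. Genes outside these rules are named as chosen after their values were seen.

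Among the bTMP lists, 6 have no peaks closer than 591 bp and 14 have peaks as close as 156 to 166 bp. All 4 S-phase lists are of the first kind, as are 2 of the 8 lists labelled 32 °C. Contrasts were therefore repeated within lists of the same spacing, a choice made after the data were examined. So was a repeat of the rrm3 tests of classes, gene lists and gene counts with the S-phase and 32 °C pairs on sen1 given the same sign, since those lists may be related. Other alternatives were the upper 50% of each list by score, lists of equal length, other flanks, peak midpoints, omission of chromosome ends and rDNA, and omission of single pairs. A value without a test was called moved when it changed by more than 1.5 times, left its binomial interval where it had one, or, for shares of bTMP peaks, moved by more than 1 SD over pairs of lists. With a pair left out, the rule for consistent change asked for 6 of 9 pairs, and within like spacing for 6 of 8, both looser than 7 of 10. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The code was tested on simulated data. With 100 tRNA genes given planted peaks in every sen1 bTMP list, tRNA genes were called in the sen1 contrast, as was the divergent intergenic class, into which planted peaks also fall, and no class was called for rrm3. For the rule of consistent change, 10 pairs were simulated by drawing the cover of each of 6002 genes at random from the bTMP lists. Of 200 genes raised by 50 percentage points, 95.0% were recovered, with 32 other genes called. The draws mixed lists of both spacings and did not keep the real pairs. The 32 is therefore no rate of false calls for the real pairs. The raise exceeds the mean differences of the bTMP genes named below, so the recovery of smaller differences was not tested. In the real pairs 37 genes were called for rrm3 and 18 for sen1.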

Results

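The series asked where RNA polymerase II and negatively supercoiled DNA lie in budding yeast lacking normal function of Sen1, a helicase that ends transcription of short non-coding RNAs, or of Rrm3, a helicase that helps replication forks past protein barriers. Rpb1 was mapped in S phase in wild type, sen1, rrm3 and sen1rrm3. bTMP was mapped in the same 4 strains in S phase, in log phase and at 32 °C. Log phase also had the 4 strains with top1, and 32 °C the 4 strains with top2-1, mutants of the topoisomerases that relax supercoils. Each strain and condition had 1 library. The Rpb1 lists held 2016 to 2136 peaks and covered 18.9% to 20.2% of the nuclear genome. The bTMP lists held 2678 to 4901 peaks and covered 7.0% to 25.9%.

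The strain loci were examined first. No peak lay over RRM3 in any of the 10 bTMP lists from rrm3 strains, while 7 of the 10 lists from strains with intact RRM3 had one, covering up to 36.7% of the gene. The 3 without one were all from 32 °C, where only top2-1 had a peak (8.61%), so the check says little about the rrm3 lists from 32 °C. Rpb1 peaks covered 14.9% of RRM3 in wild type, 51.0% in sen1 and 0% in both rrm3 and sen1rrm3. TOP1 lay under bTMP peaks in all 16 lists without top1, with 10.2% to 59.0% of the gene covered. In the 4 top1 lists it was covered in 1 only, sen1rrm3top1, at 10.8%, and which part of the gene the top1 mutation alters is not given in the sources used here. Rpb1 peaks covered 76.2% of TOP1 in wild type and 9.91% of TOP2. SEN1 had no Rpb1 peak in wild type and 0.119% of its length covered in sen1.

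In S phase, Rpb1 peaks lay over more tRNA genes in the sen1 strains than in the others. In wild type, 59 of 275 tRNA genes were touched (21.5%, exact 95% binomial interval 16.8% to 26.8%). In rrm3 the number was 62 (22.5%, 17.7% to 27.9%). It was 136 in sen1 (49.5%, 43.4% to 55.5%) and 108 in sen1rrm3 (39.3%, 33.5% to 45.3%). Relative coverage of tRNA genes was 0.868 in wild type, 0.908 in rrm3, 1.91 in sen1 and 1.53 in sen1rrm3. The sen1 and sen1rrm3 values lay above all 1000 circular shifts of their lists, which reached at most 1.37 and 1.38. Among the 80 tRNA genes touched in sen1 and not in wild type, and the 51 touched in sen1rrm3 and not in rrm3, 47 were shared, against 16.5 if these 2 pairs of separate libraries were independent over the 208 tRNA genes touched in neither wild type nor rrm3. That expectation takes each of the 208 as equally likely to be called, although some may lie nearer the peak threshold. SUP4, encoding a tyrosine tRNA, was covered at 100% in sen1 and 94.4% in sen1rrm3 by peaks on chromosome X (542952 to 543336 in sen1), with 0% in wild type and rrm3. IMT2, encoding an initiator methionine tRNA, was covered at 100% in sen1 and 66.7% in sen1rrm3. SUF5, SUP19 and SUP6 were gained in sen1rrm3 as well. IMT1 was gained in sen1 at 100% and had 0% in sen1rrm3. SUF9 was gained in all 3 mutants, with 60.2% of its length covered in sen1 and 58.3% in rrm3. TGA1 and the tRNA genes YNCC0001C and YNCK0006C were lost in rrm3 and fully covered in sen1 and sen1rrm3. Over the whole list, mean cover of the tRNA gene itself was 16.5% in wild type, 16.6% in rrm3, 44.1% in sen1 and 31.7% in sen1rrm3, with 70 genes gained in sen1, 39 in sen1rrm3 and 3 in rrm3.

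**Figure D1:**
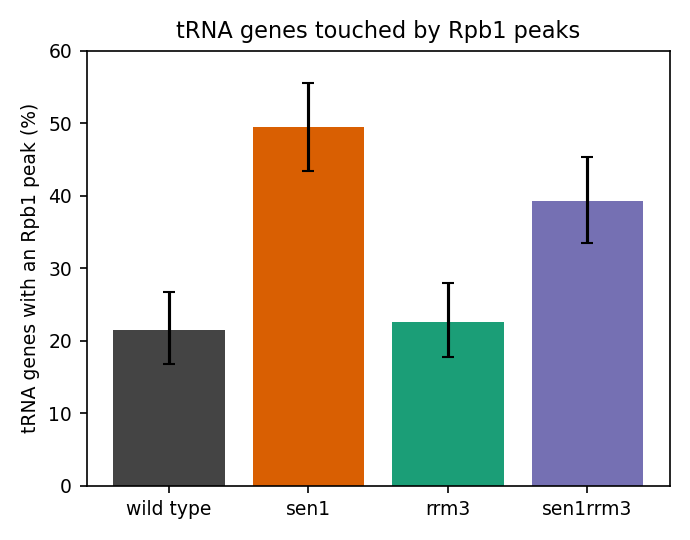
Share of the 275 nuclear tRNA genes touched by an Rpb1 peak in S phase, in percent, for 1 library per strain; bars are the shares and error bars exact 95% binomial intervals, which cover counting error only. The sen1 (49.5%) and sen1rrm3 (39.3%) bars stand above wild type (21.5%) and rrm3 (22.5%).

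Peaks over snoRNA genes ran further downstream in the sen1 strains. snoRNAs are short non-coding RNAs that guide modification of ribosomal RNA. Of the 64 snoRNA genes outside protein-coding genes with a peak in all 4 lists, 55 had a peak ending at least 500 bp further past the 3' end in sen1 than in wild type, and 52 did in sen1rrm3. In rrm3 it was 1. The median distance from the 3' end of the gene to the end of the peak was 533.5 bp in wild type, 543 bp in rrm3, 2834 bp in sen1 and 2650 bp in sen1rrm3. At the 5' side, 3 genes had a peak extended by as much in sen1, and the median distance was 268.5 bp against 297 bp in wild type. Several of these genes share a peak, and the 55 lie under 41 separate sen1 peaks. SNR13 had a peak reaching 465 bp past its end in wild type, 436 bp in rrm3, 2475 bp in sen1 and 2102 bp in sen1rrm3. At SNR33 the distances were 410 bp in wild type and 4657 bp in sen1. This measure, and the snoRNA genes named, were chosen after the peak positions had been seen. The planned class, the 500 bp downstream of snoRNA genes, was already near full cover, with relative coverage of 4.82 in wild type and 4.89 in sen1.

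The genes fixed beforehand as attenuated by Nrd1-Nab3-Sen1, the complex that stops short transcripts early, had a mean cover of 56.2% of the gene body in wild type and 56.1% in rrm3. The mean was 85.6% in sen1 and 88.7% in sen1rrm3, at percentiles 99.99 and 100 among 10000 random lists of equal size and matched wild-type cover. That percentile does not measure a change for lists with fully covered members, since ribosomal protein genes also stood at 100 in sen1 and in rrm3 and histone genes at 99.65 in sen1. With the upper score-ranked peaks the mean was higher than in wild type by 20.5 points in sen1 and 20.2 in sen1rrm3, against 29.4 and 32.5 with whole lists. ADE12, encoding adenylosuccinate synthase, had no peak in wild type or rrm3 and was covered at 85.6% in sen1 and 100% in sen1rrm3. IMD2, encoding IMP dehydrogenase, had 19.3% of its body covered in wild type and 100% in both sen1 lists, and URA8, encoding CTP synthase, had 30.4% in wild type and 98.8% in sen1 (both were chosen after their values were seen). NRD1, HRP1 and IMD3 were fully covered in every strain, URA2 was covered at 99.8% or more, and PCF11 had cover only in sen1rrm3, at 13.2%.

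Over all 6002 protein-coding genes, 113 were gained and 43 lost in sen1, 64 gained and 43 lost in sen1rrm3, and 8 gained and 13 lost in rrm3. The sen1 list shared 80.1% of its peaks with wild type (exact interval 78.4% to 81.8%), sen1rrm3 82.8% (81.1% to 84.5%) and rrm3 90.6% (89.2% to 91.8%). Of the 113 genes gained in sen1 against wild type, 49 were also gained in sen1rrm3 against rrm3, where independent calls would share 1.55 among the 3391 genes with 0% cover in both wild type and rrm3. Of the 43 lost, 11 were also lost there, against 0.581 among the 1209 genes with at least 50% cover in both. Both expectations again take every such gene as equally likely to be called. RGT1, a glucose-responsive repressor, was covered at 100% in sen1 and sen1rrm3 and 0% otherwise, by a sen1 peak on chromosome XI from 364534 to 369782. The same held for GAL11, a Mediator subunit (chromosome XV, 234221 to 238258), for MAD1, of the spindle checkpoint (chromosome VII, 345850 to 349830), and for STR2, of sulphur amino acid metabolism (chromosome X, 663627 to 667324). Peaks over SEG1, SOK2 and QDR3 covered 60.1%, 68.2% and 74.8% of the gene in sen1, with 0% in wild type. SEG1 and SOK2 were also partly covered in rrm3, at 15.7% and 21.1%. RDS1 was gained in sen1 alone. ECM32 and AZF1 were among the largest gains in sen1rrm3.

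Among the genes lost, UGP1, encoding UDP-glucose pyrophosphorylase, had 84.8% of its body covered in wild type and 86.1% in rrm3, and 0% in sen1 and sen1rrm3. STV1, of the vacuolar proton pump, RLM1, a regulator of cell wall genes, and NCL1, a tRNA methyltransferase, were likewise lost in both sen1 strains. RPM2, OPT1, SEC26 and CIT1 were lost in sen1, but each kept cover in sen1rrm3, from 28.8% for SEC26 to 92.7% for CIT1. SIT1, DBF4, ARP7 and ERC1 were lost in sen1rrm3, and ARP7 also had 0% in sen1. The largest gain in rrm3 was ATO3, covered at 96.5% in rrm3 and at 94.2% in sen1. MET14, ERG28, SPC1 and TOM6 were gained in rrm3 with 0% cover in sen1. ZRT1, a zinc transporter (79.8% in wild type, 0% in rrm3), and DIC1, a mitochondrial carrier (94.3% and 0%), led the losses. The counts depend on the peak threshold and the gene rule. With the upper score-ranked peaks only, sen1 gained 165 and lost 147 genes and rrm3 gained 44 and lost 75. Those sen1 sets held 48 of the 113 genes gained and 15 of the 43 lost with whole lists. With 80% against at most 20% cover sen1 gained 69.

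Other fixed lists held few such genes. HST3, a histone deacetylase gene of the G2/M list, was gained in sen1. RNR2, a ribonucleotide reductase gene of the DNA-damage-response list, was gained in sen1 and sen1rrm3, with 50.7% and 69.0% of its body covered, 26.3% in rrm3 and 0% in wild type. No member of the histone, G1/S, M/G1, pheromone-response, ribosomal protein, glycolysis, galactose, ribosome biogenesis, heat-shock, strain-locus or snoRNA lists was gained or lost in any mutant. Mean cover in wild type and sen1 was 98.6% and 99.5% for histone genes, 99.3% and 99.2% for ribosomal protein genes, 84.5% and 82.3% for glycolysis genes, and 93.2% and 89.9% for ribosome biogenesis genes. It was 47.6% and 53.3% for G1/S genes and 48.3% and 52.6% for heat-shock genes. Markers of other cell-cycle stages had little cover in wild type, 0.200% for G2/M, 2.39% for M/G1 and 2.14% for pheromone-response genes, and 4.95%, 14.8% and 7.11% in sen1. Their sen1 means stood at percentiles 59.05, 89.4 and 64.75 of matched random lists. DNA-damage-response genes had 3.36% in wild type and 8.67% in sen1 (percentile 62.2), and the snoRNA list had 98.7% and 98.6%. Galactose genes were at 3.31% in wild type and 2.56% in sen1.

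Rpb1 relative coverage of the stretch between divergent genes was below 1 in all 4 strains and higher with sen1. It was 0.268 in wild type and in rrm3, 0.406 in sen1 and 0.360 in sen1rrm3. Since tRNA genes lie in some of these stretches, the rise may in part repeat the tRNA gain, which was not tested. Convergent intergenic stretches had 1.75 in wild type, 1.83 in rrm3, 1.60 in sen1 and 1.66 in sen1rrm3. Ribosomal protein genes stood at 5.27 in wild type and 4.92 in sen1, and snoRNA genes at 5.26 and 4.92. Both classes were near full cover in both lists (ribosomal protein genes 99.3% and 99.2%, snoRNA genes 98.7% and 98.6%). Their lower values in sen1 thus follow the larger share of the genome under sen1 peaks (20.2% against 18.9%) and show no loss at these genes. Chromosome ends were low in each list, from 0.144 in rrm3 to 0.190 in sen1. Relative coverage around protein-coding genes was lowest 150 to 200 bp upstream of the start, at 0.420 to 0.477, and highest 50 bp before the gene end, at 1.70 to 1.8, in the 4 strains. No Rpb1 peak lay over rDNA in wild type or rrm3.

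**Figure D2:**
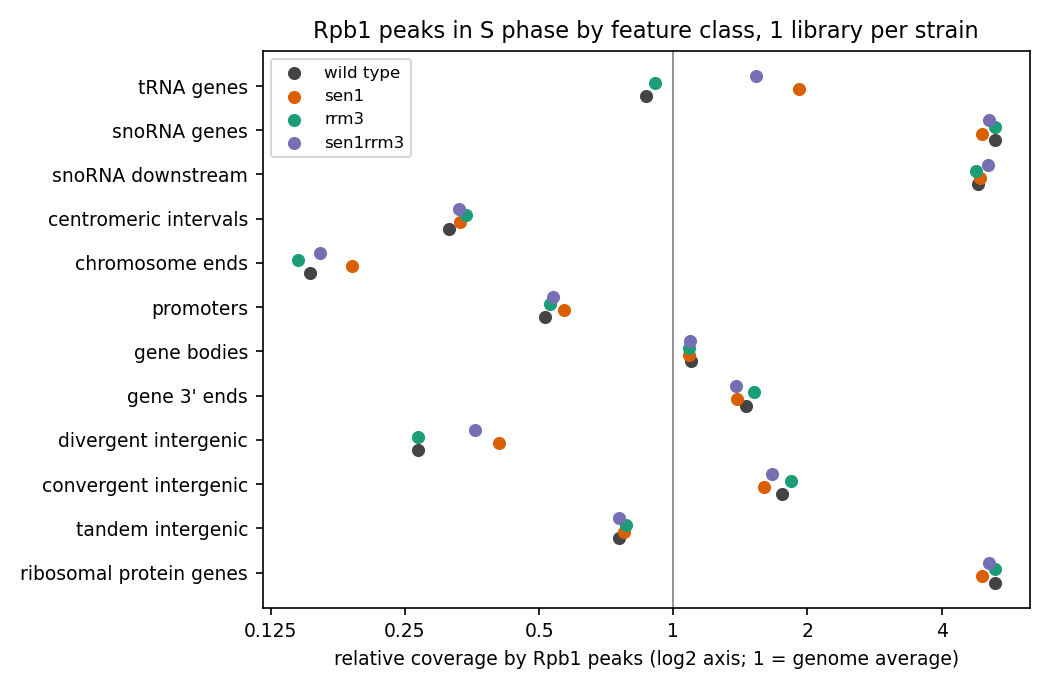
Relative coverage of 12 feature classes by Rpb1 peaks in S phase on a log2 axis, where 1 is the genome average; each point is 1 library and colours mark the 4 strains. tRNA genes and divergent intergenic stretches, classes that overlap in part, separate sen1 and sen1rrm3 (tRNA genes 1.91 and 1.53) from wild type and rrm3 (0.868 and 0.908).

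Rpb1 and bTMP peaks overlapped more than circular shifts gave in each of the 4 strains in S phase. The shared base pairs were 1.22 times those expected in wild type, 1.24 times in rrm3, 1.38 times in sen1 and 1.31 times in sen1rrm3. None of 1000 shifts per strain came as high, the highest being 1.11.

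bTMP peaks were enriched at gene starts. In all 20 lists relative coverage peaked within 50 bp of the start of protein-coding genes, at 1.34 to 2.55 times the genome average. snoRNA genes stood between 1.40 and 2.39 in the lists. In log-phase wild type, relative coverage was 2.08 for promoters, 2.17 for snoRNA genes and 1.13 for tRNA genes.

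The bTMP lists fell into 2 kinds by how close neighbouring peaks lie. In 14 lists the smallest gap was 156 to 166 bp, the median width 234 to 262 bp and the covered share 7.0% to 11.7%. In 6 lists the smallest gap was 591 to 631 bp, the median width 599 to 685 bp and the covered share 17.5% to 25.9%. The 6 were the 4 S-phase lists and those labelled sen1 and sen1rrm3 at 32 °C. The Jaccard index (shared base pairs over those in either list) had a median of 0.497 between closely spaced lists, 0.530 between widely spaced lists and 0.249 between lists of each kind. The S-phase wild-type list stood apart from the 5 other widely spaced lists, with 0.219 to 0.355. Of the paired contrasts, all 10 rrm3 pairs and the 4 top1 pairs join lists of 1 kind, 2 of the 10 sen1 pairs and 2 of the 4 top2-1 pairs mix them, and all 4 pairs of S phase against log mix them.

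**Figure D3:**
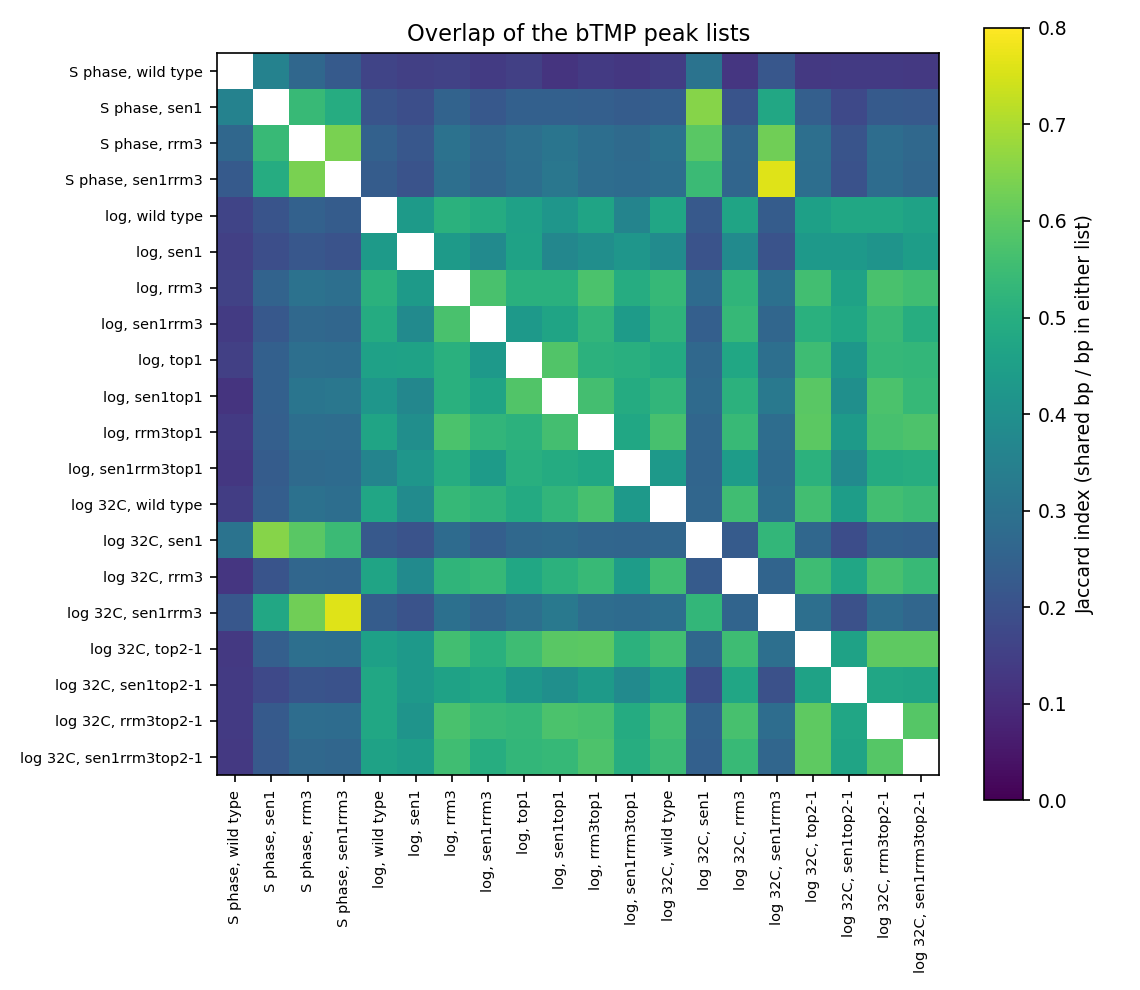
Jaccard index between the 20 bTMP peak lists, from 0 to 0.8, with growth condition and strain on both axes and the diagonal left blank. The lists labelled sen1 and sen1rrm3 at 32 °C overlap most with the S-phase lists of the same strain, at 0.656 and 0.761.

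The rrm3 pairs ask whether cover by bTMP peaks shifts with rrm3 on average over the backgrounds. Ribosomal protein genes had lower relative coverage with rrm3 in 9 of 10 pairs, with a mean log2 difference of -0.36 ± 0.30 (SD, n = 10 pairs; exact sign-flip permutation p = 0.00391, adjusted p = 0.0469 over 12 classes). In S phase the value was 1.59 in wild type and 0.847 in rrm3. This is the largest of the 10 differences (-0.90) and uses the S-phase wild-type list, which stands apart from the other widely spaced lists, and without this pair the mean was -0.30. In log phase it was 1.19 in wild type and 0.982 in rrm3, and 1.37 in sen1 against 0.786 in sen1rrm3. The exception was sen1top1 in log phase, with 0.740 against 0.775 in sen1rrm3top1. The difference was -0.69 in S phase, -0.32 in log phase and -0.24 at 32 °C. The call was lost with lists of equal length (-0.39, exact permutation adjusted p = 0.164), with the upper score-ranked peaks (-0.38, adjusted p = 0.897, lower in 6 of 10 pairs) and when any 1 of 9 pairs was left out (adjusted p of 0.0938 to 0.102, exact permutation). It was also lost when the S-phase and 32 °C pairs on sen1, whose lists overlap most strain by strain, were given the same sign (adjusted p = 0.0938, exact permutation). Without the log-phase sen1top1 pair it held (-0.41, exact permutation adjusted p = 0.0469). With 1 pair going the other way, neither 9 pairs nor the pairs given the same sign could pass over 12 classes, as no other class came near. Those losses follow from the number of sign patterns, and the mean stayed at -0.41 to -0.30 with a pair left out. None of the other 11 classes passed, with adjusted p of 0.703 or more. No shift of the covered share was detected, with a mean log2 difference of 0.0071 ± 0.26 (SD, n = 10 pairs, exact permutation p = 0.951).

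**Figure D4:**
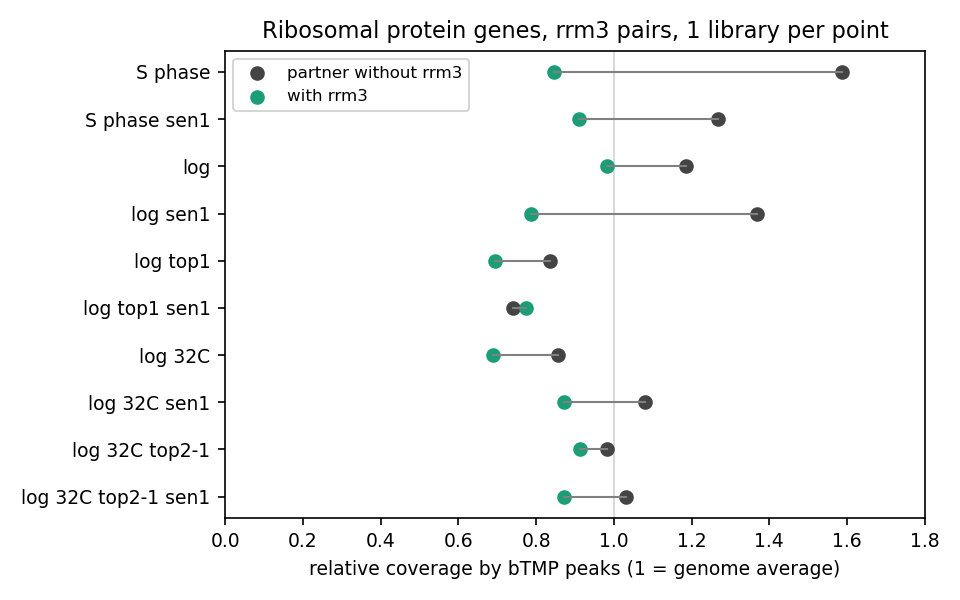
Relative coverage of ribosomal protein genes by bTMP peaks in each rrm3 pair, where 1 is the genome average; each point is 1 library, grey lines join the pair, and row names give the growth condition and shared background. The rrm3 member is lower in 9 of 10 pairs.

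Gene by gene, 37 genes were consistently changed with rrm3, 12 higher and 25 lower. With lists of equal length the split was 25 higher and 18 lower, and without the 32 °C pair on wild type, under a rule of 6 of 9 pairs, 62 higher and 49 lower. ATG16, an autophagy gene, was lower in 8 of 10 pairs, with a mean difference of -36.5 ± 25.6 percentage points of the gene and its upstream 300 bp (SD). MEH1, EMC6, SOR1, UBX6 and SCW4 were also lower in 8 pairs. The silent mating cassette gene HMLALPHA2 was higher in 8 pairs, by 24.0 ± 25.1 points, and REV7, a translesion polymerase subunit, in 8 pairs by 14.9 ± 20.1 points. MATALPHA2 was higher in 7, and as it shares sequence with the silent cassette the 2 cannot be counted as separate loci. With sen1, 18 genes were consistently changed, 17 of them higher. MSL1, encoding a U2 snRNP protein, was lower in 8 pairs, with a mean difference of -24.2 ± 24.5 points, and EFM6 and VPS501 were higher in 8 pairs. HMLALPHA2 and NOP15 were higher in 7. YLR410W-B, YDR210C-D, YML039W and YBL005W-B, also higher, are Ty retrotransposon genes present in many near-identical copies, so their positions are uncertain, as are those of YLR227W-B and YBR012W-B among the genes higher with rrm3. Within the 8 pairs of like spacing, 8 genes met the rule for sen1, 5 higher and 3 lower, 4 of them shared with the full set. For the upstream stretch alone 3 were higher and 6 lower.

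In the sen1 pairs, no class passed the test. All 12 classes tested had an adjusted p of 0.502 or more, and none an unadjusted p under 0.05, by the exact sign-flip test. tRNA genes had a mean log2 difference of -0.10 ± 0.70 (SD, n = 10 pairs) and ribosomal protein genes 0.033 ± 0.25. The tRNA mean averages values of opposite sign, -0.60 over the 4 log pairs and 0.41 over the 4 pairs at 32 °C. At 32 °C the 2 pairs of like spacing had 0.74 and -0.093. The rDNA repeat could not be tested, since log-phase sen1 had 0% of it covered, against 71.9% in log-phase wild type. The covered share had a mean log2 difference of 0.30 ± 0.69 (SD, n = 10 pairs, exact permutation p = 0.234). In the 8 pairs of like spacing, tRNA genes had -0.25 ± 0.71 and the covered share 0.0052 ± 0.33 (exact permutation p = 0.938). The sen1 by rrm3 interaction was 0.028 ± 0.42 on log2 covered share (SD, n = 5 squares, exact permutation p = 0.875) and -0.22 ± 1.03 for tRNA genes, and -0.033 ± 0.46 and -0.29 ± 1.17 in the 4 squares of like spacing.

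For the contrasts of top1, top2-1 and growth condition, the classes given here were picked after the values of all classes had been seen. In the top1 pairs, 4 in log phase, bTMP relative coverage was lower with top1 in 4 of 4 pairs at tRNA genes (mean log2 difference -0.90 ± 0.82, SD), downstream of snoRNA genes (-0.47 ± 0.13), at ribosomal protein genes (-0.48 ± 0.35) and at promoters (-0.39 ± 0.32). Each had an exact permutation p of 0.125, the smallest that 4 pairs allow, and an adjusted p of 0.300, so no call was possible. Downstream of snoRNA genes the difference was -0.10 with the upper score-ranked peaks and -0.29 with lists of equal length. tRNA genes had -0.58 when widened by 500 bp in place of 100 bp, and -0.60 without the sen1rrm3 pair, whose top1 list is the one with a peak over TOP1. They stood at 1.13 in wild type and 0.437 in top1, and at 0.796 in sen1rrm3 and 0.229 in sen1rrm3top1. The covered share had a mean log2 difference of 0.28 ± 0.26 (exact permutation p = 0.25, n = 4 pairs).

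With top2-1 at 32 °C, tRNA genes were lower in 4 of 4 pairs (-0.88 ± 0.35, SD) and snoRNA genes higher in 4 of 4 (0.38 ± 0.22), both with an exact permutation p of 0.125, where 2 of the pairs mix list kinds. With tRNA genes widened by 500 bp the difference was -0.18. In the 2 pairs of like spacing tRNA genes had -0.79 ± 0.58 and snoRNA genes 0.23 ± 0.23. The covered share had -0.78 ± 1.04 in all 4 pairs and 0.10 ± 0.14 in those 2. Between 32 °C and log phase, snoRNA genes were lower in 4 of 4 strains (-0.27 ± 0.25, exact permutation p = 0.125), and had -0.14 ± 0.11 in the 2 strains of like spacing. With peak midpoints the snoRNA difference was 0.97 for top2-1 and -0.78 for 32 °C against log. The covered share had 0.77 ± 0.94 in 4 strains and -0.012 ± 0.42 in those 2. In S phase against log, tRNA genes were higher (0.81 ± 0.48) and centromeric intervals lower (-0.98 ± 0.58) in 4 of 4 strains, with a covered share higher by 1.34 ± 0.25. With wider flanks around both classes the differences were 0.074 for tRNA genes and -0.44 for centromeric intervals. Every S-phase list is widely spaced and every log list closely spaced, so growth condition and list kind cannot be told apart there.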

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

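The test of the 32 °C lists for a sen1 effect, the bound for the counts over sign patterns, the test of the change per pair with lists of equal length and the tests with 2 pairs given the same sign were chosen only after the results were seen, and the overlaps between lists had been seen before the window tests. Mitochondrial peaks, which no comparison used, were more numerous in 6 bTMP lists than in the wild-type list of the same growth condition: 7 in sen1, 9 in rrm3 and 6 in sen1rrm3 in S phase against 0, and 3 in rrm3, 18 in sen1rrm3 and 3 in rrm3top1 in log phase against 1. The wild-type list served as the control. At 32 °C it had 11, and the Rpb1 lists had 0. Of 26 exact permutation tests of whether an effect of sen1 or rrm3 differed between log phase and 32 °C, 0 passed (smallest p = 0.0857, for tRNA genes with sen1 at -0.60 in log phase and 0.41 at 32 °C, where 2 of the 4 pairs mix list kinds; a p of 0.0286 was possible, and smallest adjusted p = 1).

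The bTMP lists labelled sen1 and sen1rrm3 at 32 °C have the wide peak spacing of the S-phase lists. Reducing each list to 250 bp around its 1000 highest-scored peaks, the S-phase list of the same strain touched more of these windows than any other list, 55.7% for sen1 and 69.4% for sen1rrm3, against at most 45.4% and 53.9% for S-phase lists of other strains and 24.6% and 31.9% for closely spaced 32 °C lists. Peak names in both lists carry the tag IPB, and those of the S-phase lists IPA. Peak names in the other 32 °C lists and in the log lists give the strain with neither tag. The 2 lists may thus come from the S-phase experiment, but a run of the 32 °C libraries with the S-phase settings cannot be told apart from this, since no S-phase list was called with close spacing and no other 32 °C list with wide spacing. An effect of sen1 at 32 °C cannot be told apart either, as the only other 32 °C lists with sen1, with a smallest gap of 158 bp, also carry top2-1. Strain loci were mixed for the list labelled sen1 at 32 °C. Its cover of RRM3 was 0%, as in 32 °C wild type, against 36.7% in S-phase sen1. For TOP1 it was 42.2%, against 10.2% in 32 °C wild type and 59.0% in S-phase sen1. For TOP2 it was 0%, as in S-phase sen1, against 9.38% in 32 °C wild type. The list labelled sen1rrm3 at 32 °C had 16.07% of TOP2 covered, against 16.05% in S-phase sen1rrm3 and 9.70% in 32 °C rrm3. Its cover of TOP1 was 13.9%, as in S-phase sen1rrm3, but 32 °C rrm3 was close at 14.3%. Its cover of SEN1 was 0%, against 3.42% in S-phase sen1rrm3 and 2.36% in 32 °C rrm3.

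The larger number of tRNA genes under Rpb1 peaks in sen1 was set against 2 technical explanations. With all Rpb1 lists at equal length, the sen1 over wild-type ratio of tRNA relative coverage was 2.22, so the longer sen1 list does not account for it. Of the 80 tRNA genes newly touched in sen1, 20.0% (exact interval 11.9% to 30.4%) lay under a peak that also overlapped a wild-type peak, which argues against widening of neighbouring peaks as the main source. The other 64 lay under peaks of their own. A biological origin in loss of Sen1 therefore stays as a hypothesis from 1 library per strain, and differences in depth, antibody yield or background between immunoprecipitates were not tested.

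Lower bTMP coverage of ribosomal protein genes with rrm3 had a mean log2 difference of -0.36 ± 0.30 (SD) with whole lists and -0.39 ± 0.41 with lists of equal length, lower in 9 of 10 pairs in both. The call ended there, with a larger SD, but the change per pair was -0.026 ± 0.20 (SD, n = 10), where 0.18 would be needed to end 50% of the difference, which argues against unequal lengths as the main source. A shift shared by all genes under S-phase Rpb1 peaks was tested on 760 others with at least 80% of the body covered in wild type. They were lower with rrm3 in 6 of 10 pairs (mean log2 difference 0.041 ± 0.19, SD, exact permutation p = 0.504), which argues against such a shared shift. Rpb1 was mapped only in S phase, while most of the pairs are from other growth conditions. Peak cover does not give the amount of polymerase, so a shift confined to the most transcribed genes was not tested. Lists of genes did not sort by S-phase Rpb1 cover in wild type, with -8.88 ± 11.1 points of bTMP cover (SD) for glycolysis genes (84.5% Rpb1 cover) and -4.71 ± 4.17 for galactose genes (3.31%), but 2.58 ± 8.65 for histone genes (98.6%) and 1.24 ± 4.19 for ribosome biogenesis genes (93.2%). These points are over the gene body plus 300 bp upstream and are not divided by the covered share. They are thus another measure than the log2 differences above. Depth is unknown. The call also ended when any 1 of 9 pairs was left out, and when 2 possibly related pairs were given the same sign (adjusted p = 0.0938, exact permutation). With 1 pair going the other way, these losses were fixed by the number of sign patterns. The mean stayed at -0.41 to -0.30 with a pair left out. The call may still be chance, as it passed narrowly (exact permutation adjusted p = 0.0469) and ended with the upper score-ranked peaks.

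For genes consistently changed in bTMP, 27 of 100 sign patterns of the pairs gave at least the 18 genes of sen1, with up to 67 in another pattern, so chance cannot be excluded for sen1. For rrm3, 2 of 100 patterns gave at least the 37 genes observed, the real one included, with 38 in the highest other. That share is under 0.05, but with the S-phase and 32 °C pairs on sen1 given the same sign 5 of 100 patterns gave as many, with 49 in the highest other, so chance cannot be excluded for rrm3 if those lists are related.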

How the results depend on the processing

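The comparisons within lists of like spacing, the tests with 2 pairs given the same sign and the tests of snoRNA peaks were chosen only after the results were seen. Depth is unknown for every list, so the settings below vary only how peaks and pairs are used, and 1 library per group leaves no replicate to omit. Of 282 values under another setting, 225 kept their direction and side of the threshold or their size, 10 lost a call, 34 moved and 13 changed sign. Of 143 with a pair or square left out, 100 kept it, 9 lost a call, 28 moved and 6 changed sign. Both tallies include values that could not change. In contrasts with too few pairs to reach the threshold, no class or covered share can pass under any setting. The shares that kept it are thus no measure of robustness. The cause of the changes was not tested unless stated.

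On log2 covered share, where no contrast passed its test, signs changed as follows. With log pairs alone sen1 had -0.0052 (against 0.30), rrm3 -0.045 (against 0.0071) and the interaction -0.068 (against 0.028). With 32 °C pairs alone rrm3 had -0.022, with the upper score-ranked peaks -0.012, and without top mutations the interaction had -0.19. Within like spacing top2-1 had 0.10 (against -0.78), 32 °C against log -0.012 (against 0.77) and the interaction -0.033. The number of peaks in place of the covered share gave -0.042 for sen1, 0.073 for top2-1, -0.074 for 32 °C against log and -0.25 for S phase against log. With a pair left out, sen1 ranged from 0.15 to 0.39, rrm3 from -0.038 to 0.042, top1 from 0.21 to 0.41, top2-1 from -1.11 to -0.42, 32 °C against log from 0.51 to 1.13, S phase against log from 1.27 to 1.44 and the interaction from -0.088 to 0.16.

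For bTMP relative coverage with rrm3, 0 classes passed in place of 1 with the upper score-ranked peaks, lists of equal length, S-phase, log or 32 °C pairs alone, and pairs without top mutations, and 0 to 1 with a pair left out. Ribosomal protein genes then had -0.38, -0.39, -0.69, -0.32, -0.24 and -0.51, in that order, and -0.41 to -0.30 with a pair left out. Single conditions hold 2 or 4 pairs, which cannot reach 0.05, and with the 6 pairs without top mutations 1 class alone cannot pass after adjustment. Nor can it with 9 pairs of which 1 goes the other way, or with 2 pairs given the same sign while 1 goes the other way. With the S-phase and 32 °C pairs on sen1 given the same sign the value stays at -0.36 by construction and the call ended (exact permutation adjusted p = 0.0938). So did the calls on mean cover of ribosomal protein (-3.24 points), glycolysis (-8.88) and galactose genes (-4.71), each with an exact permutation adjusted p of 0.0677. Giving 2 pairs the same sign leaves fewer sign patterns, which raised p in each case with the differences unchanged. Peak midpoints (-0.26, exact permutation adjusted p = 0.0234) and omission of chromosome ends (-0.36, exact permutation adjusted p = 0.0430) kept the call.

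Rpb1 gene counts moved with the upper score-ranked peaks, to 147 lost in sen1, 44 gained and 75 lost in rrm3, and 108 gained and 136 lost in sen1rrm3. With 80% against at most 20% cover, sen1 gained 69, rrm3 gained 4 and lost 5, with 1 tRNA gene gained, and sen1rrm3 lost 19. With the upstream stretch included, sen1 gained 72 and lost 15, rrm3 gained 3 and lost 3, with 1 tRNA gene gained, and sen1rrm3 lost 18. Peaks shared with wild type over at least 50% of their length made up 70.9% in sen1, 88.0% in rrm3 and 74.0% in sen1rrm3. The median share of bTMP peaks shared, 80.2% between widely and 71.4% between closely spaced lists, was 65.9% between widely spaced lists at that overlap, and with the upper score-ranked peaks 66.1% between widely and 57.3% between closely spaced lists. For snoRNA peaks longer by 1000 bp, rrm3 had 0, sen1 48 and sen1rrm3 44. The upper score-ranked peaks and lists of equal length left the peaks over all 64 snoRNA genes as they were, so these settings tested nothing there.

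The bTMP genes consistently changed with sen1 were 8 within like spacing, 141 when any difference counted and 9 for the upstream stretch alone. Higher and lower genes numbered 17 and 1 for sen1, but 5 and 3 within like spacing and 3 and 6 for the upstream stretch alone, and for rrm3 12 and 25, but 25 and 18 with lists of equal length. With rrm3 they were 171 when any difference counted, 19 of them among the 37. Of the 37, 6 were among the 25 called with the upper score-ranked peaks, 17 among the 43 with lists of equal length and 8 among the 27 for the upstream stretch alone. With a pair left out they numbered 23 to 102 for sen1 and 61 to 112 for rrm3, under the looser rule of 6 of 9 pairs.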

Other observations

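The tests in this part, and the genes named beside snoRNA genes, were chosen only after the gained genes and the class values had been seen. In sen1, 11 of the 113 gained genes lay under a peak that also covered a snoRNA gene upstream on the same strand, and in sen1rrm3 9 of 64, with 0 of 8 in rrm3. They included RGT1 and AIM26 after SNR69, GAL11 after SNR81, MAD1 after SNR10, REC104 after SNR71 and UBX6 after SNR60. The 9 genes of sen1rrm3 are all among the 11 of sen1. With only 8 genes gained, the 0 in rrm3 cannot set it apart, and the share over all genes was not counted. The snoRNA genes whose peak was longer past the 3' end by at least 500 bp numbered 55 in sen1 and 1 in rrm3, and 3 in sen1 were as much longer at the 5' end. These values are consistent with the hypothesis that polymerase runs on past snoRNA genes when Sen1 function is lost and that some gained genes mark this run-on. A peak list gives neither strand nor RNA, so initiation within the extended stretch remains open.

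UGP1, lost in both sen1 strains, follows RGT1 and AIM26 on chromosome XI. The wild-type peak over UGP1 ran from 370119 to 371459 on that chromosome, and the sen1 peak over RGT1 ended at 369782.

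In the fixed lists, mean bTMP cover with rrm3 was lower for glycolysis genes, with a mean difference of -8.88 ± 11.1 percentage points (SD over 10 pairs, lower in 9, exact permutation p = 0.00586, adjusted p = 0.0339 over 13 lists). Galactose genes had -4.71 ± 4.17 points (lower in 9 of 10 pairs, adjusted p = 0.0339, exact permutation) and ribosomal protein genes -3.24 ± 2.79 points (lower in 8 of 10, adjusted p = 0.0339, exact permutation). Heat-shock genes had -2.14 ± 2.71 points (adjusted p = 0.121, exact permutation). The other 9 lists had adjusted p of 0.183 or more, and with sen1 all 13 lists had 0.375 or more. These means are not divided by the covered share of the genome, and single members rarely met the rule for consistent change: 1 ribosomal protein gene was lower and 1 higher, and 1 ribosome biogenesis gene was higher. Lists of equal length, the upper score-ranked peaks and omission of single pairs were not applied to these means. With the S-phase and 32 °C pairs on sen1 given the same sign, as those lists may be related to each other, 0 of the 13 lists passed with rrm3 (smallest adjusted p = 0.0677, exact permutation, -8.88 points for glycolysis genes as before). Fewer sign patterns remain there, which raised p for these 3 lists with the differences unchanged.

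The 47 tRNA genes with Rpb1 peaks in both sen1 strains and in neither other strain were touched by S-phase bTMP peaks in 36.2% of cases in wild type, 48.9% in sen1, 44.7% in rrm3 and 44.7% in sen1rrm3. The 228 other tRNA genes were touched in 22.8%, 33.8%, 33.8% and 28.5%.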
